A study of Alveopora daedalea with 48 samples.

How the data were processed

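PolyA RNA was sequenced from 48 nubbins of *Platygyra daedalea*, which the submitters' organism field names *Alveopora daedalea*. Per the labels' protocols, RNA was extracted with an RNeasy Plant kit, libraries were made from 500 ng with the Illumina Stranded mRNA Prep and sequenced on 2 NovaSeq lanes. Per the submitters' processing notes, FastQC 0.12.0, fastp 0.23.2 and STAR 2.7.10b were used. The counting program, its strand setting, its treatment of reads that span exons and the genome builds are not given in the sources used here. The deposited values were whole-number counts per exon, not normalized, in a symbiont table of 772014 exons from 45029 genes and a host table of 140484 exons from 25004 genes. Reads shared between near-identical genes, or between the native symbionts and the *C. proliferum* gene models, could not be told apart from these counts.

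Counts were summed over the exons of a gene. The table columns name a nubbin's inoculation treatment, temperature, colony and number, which place each library in 1 of 10 groups without tying it to a single sample record. Host totals had a median of 10184821 counts in ambient libraries (6561410 to 12107185) and 17183655 in elevated libraries (7908602 to 22214368). Symbiont totals had a median of 6283898 counts in ambient libraries (2979056 to 8466271) and 1669390 in elevated libraries (43357 to 8114193). Wilson 95% intervals of each library's symbiont share cover counting error only and are far narrower than the spread between nubbins. In 93 pairs of libraries of the same group, the counts differed by at least 7.9 in chi-square per gene, so no library was counted as a copy of another.

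Tests, samples and terms were fixed before the data were examined, apart from the alternatives named as added. Gene counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM normalization, filterByExpr (minimum count 10, minimum total 15), a term per group and a term per colony, and Benjamini-Hochberg adjustment at 0.05. The host fit took all 48 libraries and 19922 genes after the filter removed 5082, for 15 contrasts. The symbiont fit took the 28 WT10, SS1 and SS8 libraries and 23606 genes after the filter removed 21423, for 10 contrasts. The C and RIC libraries were left out of it because their native symbionts need not be *C. proliferum*. Adjusted p-values of genes are edgeR's unless DESeq2 1.42.0 is named. Expression of single genes is given as normalized CPM.

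Symbiont share was the percent of symbiont counts among symbiont and host counts, tested by exact two-sided permutation over all arrangements of the libraries and adjusted over 5 treatments. Permutational analysis of variance (vegan 2.7.1, adonis2, 9999 permutations, marginal shares of variance) and principal components used log2 CPM with a prior count of 2. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of called genes shared between contrasts was set beside that of independent lists, the product of both counts over the genes tested, summed over directions.

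Libraries were paired by colony name, as the labels give it, and colony L held 2 sets of host libraries. The libraries of a colony in a group were averaged, and the mean over the colonies of that group was removed. For the same colony in different groups, these deviations correlated across genes at 0.39 to 0.91 (median 0.75, 135 pairs). For different colonies in different groups they correlated at -0.55 to -0.18 (median -0.38, 270 pairs). The deviations within a group cancel out, so negative values between colonies follow wherever colony effects repeat across groups. The negative values are therefore no separate evidence for the pairing. Genes are not independent replicates in these correlations.

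Counts were simulated with 200 changed genes, all drawn from those at or above the median expression, so the recovery does not cover weakly expressed genes. The host test of heat in WT10 recovered 14.9%, 56.7% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 8 false among 121 calls. The host test of SS1 against WT10 in heat response recovered 4.5%, 22.4% and 84.8%, with 8 false among 82 calls. The symbiont test of heat in WT10 recovered 9%, 47.8% and 86.4%, with 2 false among 97 calls, and that of SS1 against WT10 in heat response 0%, 14.9% and 68.2%, with 3 false among 58 calls.

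The alternatives tried were DESeq2, RLE normalization, no low-count filter, no colony term, nubbins of a colony summed or averaged, only the compared groups fitted, all 48 libraries in the symbiont fit, other distances and gene sets in the analysis of variance, a log2 ratio of symbiont to host counts, permutation within colony, and each library left out in turn. Added after the data were examined were colony L as 2 blocks, host counts thinned to the lowest total, a composition covariate, the native symbionts of 20 C and RIC libraries fitted alone, and the omission of doubted libraries (elevated SS1 L1334 from both tables, ambient RIC I989 and J1028 and ambient C J1096 from the host table, elevated SS8 L1322 from the symbiont table). The covariate was the percent of symbiont counts in exons without a count in ambient C libraries. The doubted libraries followed no rule set beforehand. Only I989 and J1028 were among those found far from the rest of their group, J1028 on a symbiont measure alone. Each count of calls was also set beside 22 splits of the compared libraries, the real one included. They were drawn without regard to colony, with the other libraries kept in the fit. A first set of splits had been run in fits of the compared groups alone. It was replaced before writing because those fits do not give the reported counts.

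The genes to be named were set beforehand: of called genes with the same sign in all 3 colonies and a mean expression at or above the median, those with the largest rise and fall. Because the identifiers are not paired with gene names in the files and no reference was used here, at most 2 that rose and 2 that fell are named per organism, from heat in C for the host and heat in WT10 for the symbiont. Pdae9495 and evm.model.scf7180000356980.13 are named because each is the sole gene of its contrast, chosen after their values were seen. For the same reason none of the 19 gene lists fixed beforehand could be tested.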

Results

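The data were counts of polyA RNA from nubbins (small fragments) of the reef coral *Platygyra daedalea*, read against gene models of the coral host and of *Cladocopium proliferum*, a dinoflagellate alga that lives inside coral cells. Nubbins of 3 colonies (I, J and L) fell into 5 inoculation treatments. C nubbins were never bleached or inoculated. The other nubbins were chemically bleached with menthol and diuron and then given native symbionts (RIC), the wild-type *C. proliferum* strain WT10, or the heat-evolved strains SS1 or SS8. Each treatment was held at 27 °C (ambient) or ramped to 32.2 °C (elevated) and sampled after 4.9 eDHW, the submitters' unit of accumulated heat exposure. The 48 libraries comprised 6 ambient and 4 elevated C libraries, 5 and 5 of RIC, 5 and 5 of WT10, 4 and 5 of SS1, and 5 and 4 of SS8. Nubbins are named here by colony and number (L1334). A library held between 11429401 and 24073982 counts over both organisms, of which host counts made up 6561410 to 22214368 and symbiont counts 43357 to 8466271. Several nubbins came from the same colony and the inoculation treatments were kept in separate tanks, so the p-values measure the spread between nubbins, and an inoculation treatment cannot be told apart from its tank. The gene models carry identifiers without names or coordinates in the files, so no gene could be matched to the 19 gene lists fixed beforehand, and genes are described by number, direction and size.

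The share of symbiont counts was compared between temperatures as a measure of how much counted RNA came from the alga. Counts were deposited per exon, and the sources used here do not say whether a read that spans exons was counted more than once. Tested symbiont genes had a median of 17 exons and tested host genes 4, so such counting would raise the level of every share. The mean share was lower at 32.2 °C in all 5 treatments, and the difference passed the test in 4 of them. In C libraries it was 39.4% ± 3.59 (SD, n = 6) at ambient and 7.61% ± 3.69 (SD, n = 4) at elevated temperature. In RIC libraries it was 40.1% ± 7.47 (SD, n = 5) against 5.17% ± 4.46 (SD, n = 5), in WT10 libraries 34.9% ± 3.35 (SD, n = 5) against 10.6% ± 2.43 (SD, n = 5), and in SS8 libraries 32% ± 6.65 (SD, n = 5) against 8.34% ± 5.29 (SD, n = 4). In each of these 4 treatments every elevated library lay below every ambient library (exact two-sided permutation tests, adjusted p = 0.00992 each over 5 tests). In SS1 libraries the share was 40.4% ± 9.87 (SD, n = 4) against 23.9% ± 16.7 (SD, n = 5), and the difference of -16.4 percentage points did not pass (exact permutation p = 0.135). The elevated SS1 nubbin L1334 held a share of 50.6%, and without it the difference was -23.09 points (exact permutation test, adjusted p = 0.0286). Within each colony the mean share was lower in elevated than in ambient libraries in all 5 treatments, by between -37.1 and -5.61 points. With the nubbins of a colony averaged, the smallest exact permutation p that 3 colonies allow is 0.1, so no treatment could pass.

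**Figure D1:**
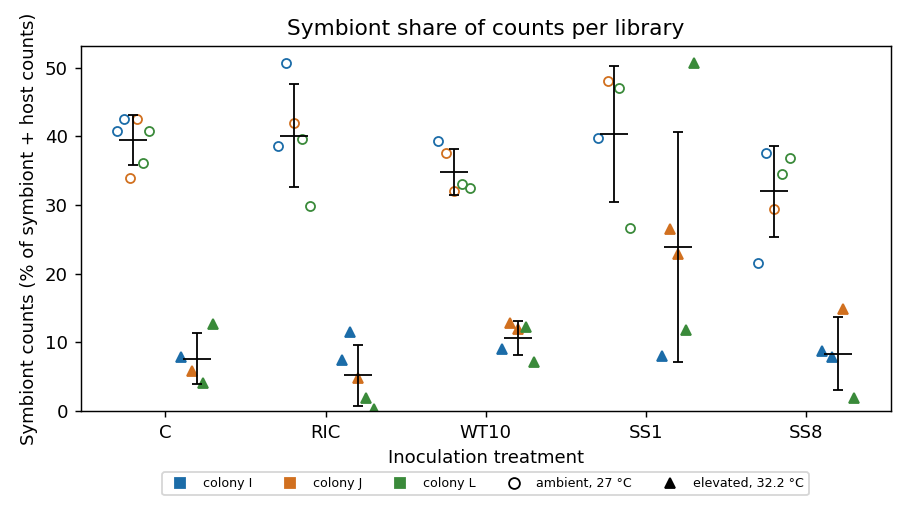
Symbiont counts as a percent of symbiont plus host counts (y axis) for each library, by inoculation treatment (x axis). Open circles are ambient and filled triangles elevated libraries, colours are colonies, and black bars give the mean and SD of a group. The elevated SS1 library of nubbin L1334, at 50.6%, lies with the ambient libraries.

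Whether heat lowered the share by a different amount between treatments was tested by permuting inoculation labels within each temperature. The fall in WT10 libraries was 7.58 points smaller than in C libraries, which did not pass after adjustment over 4 tests (exact permutation p = 0.0193, adjusted p = 0.077). The fall was 7.84 points smaller in SS1 than in WT10 libraries (exact permutation p = 0.476, adjusted p = 0.644) and 1.16 points smaller without nubbin L1334 (exact permutation p = 0.865). The corresponding difference between SS8 and WT10 libraries was 0.609 points (exact permutation p = 0.891). RIC and C libraries differed by -3.1 points (exact permutation p = 0.483).

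Colony accounted for most of the variance in host expression. In a permutational analysis of variance on log2 CPM (counts scaled to a common library total), colony went with 50.41% of the host variance (permutation p = 0.0001, the smallest the permutations can give), inoculation with 6.34% (permutation p = 0.0265), temperature with 4.33% (permutation p = 0.0005) and their interaction with 4.19% (permutation p = 0.2946). The inoculation term did not pass when the nubbins of a colony were averaged (permutation p = 0.1497). With 1 minus Spearman's correlation as the distance, inoculation went with 6.49% (permutation p = 0.0002) and the interaction passed, at 3.14% (permutation p = 0.0284). The host libraries of colony L formed 2 sets, the 7 from nubbin L1258 to L1290 and the 12 from L1304 to L1340 in order of their numbers. The median dissimilarity (1 minus Spearman's rho across genes, which are not independent replicates) between these sets was 0.111, close to the 0.12 between colonies I and J, while within a set it was 0.0438 and 0.0428. All C and WT10 nubbins of colony L belonged to the higher-numbered set. With these sets as separate blocks, the inoculation term went with 3.85% of the variance (permutation p = 0.097). In the symbiont counts of WT10, SS1 and SS8 libraries, temperature went with 13.29% of the variance (permutation p = 0.001), inoculation with 6.77% (permutation p = 0.3694) and colony with 6.87% (permutation p = 0.3692).

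**Figure D2:**
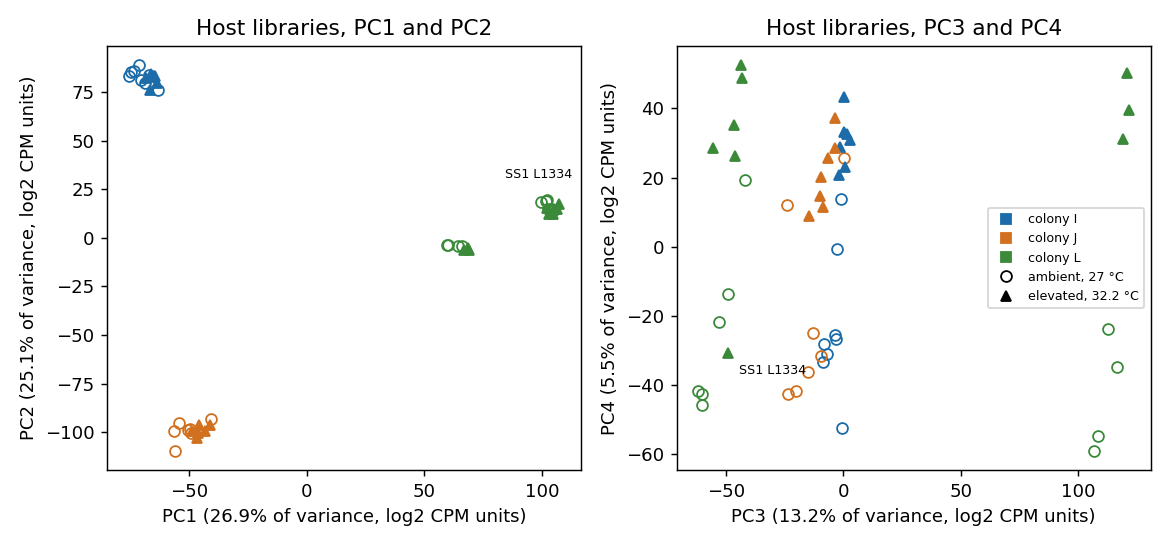
Principal components of host log2 CPM over 48 libraries, PC1 against PC2 (left) and PC3 against PC4 (right), in log2 CPM units with the percent of variance on each axis. Symbols and colours are as defined in the key; colony L splits along PC1 and PC3, and the elevated SS1 library L1334 lies among ambient libraries on PC4.

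Host genes were called for heat in each of the 5 treatments. Of 19922 host genes tested, 292 were called in C libraries (189 rose and 103 fell), 1715 in RIC (718 rose and 997 fell), 865 in WT10 (403 and 462), 127 in SS1 (90 and 37) and 389 in SS8 (181 and 208), by edgeR's quasi-likelihood test at an adjusted p below 0.05. In total 22 genes were called in all 5 contrasts, of which 16 rose and 6 fell. Of the 1882 genes called in 1 treatment alone, 1061 had the same sign in all 5, and of the 418 called in 2 treatments, 355 had. C and WT10 libraries shared 174 called genes, all in the same direction, where independent lists of those sizes would share 6.2. RIC and WT10 shared 382 in the same direction against 37.6 for independent lists, and SS1 and SS8 shared 39 against 1.2. Of the 127 genes called in SS1, 80 were shared with WT10 in the same direction against 2.7, and 67 with RIC against 5.1. RIC and SS8 shared 162, of which 158 had the same direction. Their fold changes correlated at a Pearson's r of 0.04 and a Spearman's rho of 0.19 across genes, which are not independent replicates. The heat contrasts in RIC and SS8 part the host sets of colony L in opposite directions, which the colony term does not remove. How far this lowered the correlation was not tested, so a low value does not show unrelated responses. The 5 heat contrasts have no library in common, although 1 fit gave them a common spread and common colony terms. The 92 genes that were called in at least 3 treatments and rose had a median log2 fold change of 1.06 in C, 1.06 in RIC, 1.08 in WT10, 0.94 in SS1 and 0.92 in SS8 libraries. The 100 that fell had medians of -1.17, -1.37, -1.33, -0.70 and -1.18. Because these genes were chosen by their calls, the sizes are not independent of the choice. The SS1 medians include elevated nubbin L1334, whose host expression resembled that of ambient libraries. A weaker host response in SS1 therefore cannot be read from them.

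**Figure D3:**
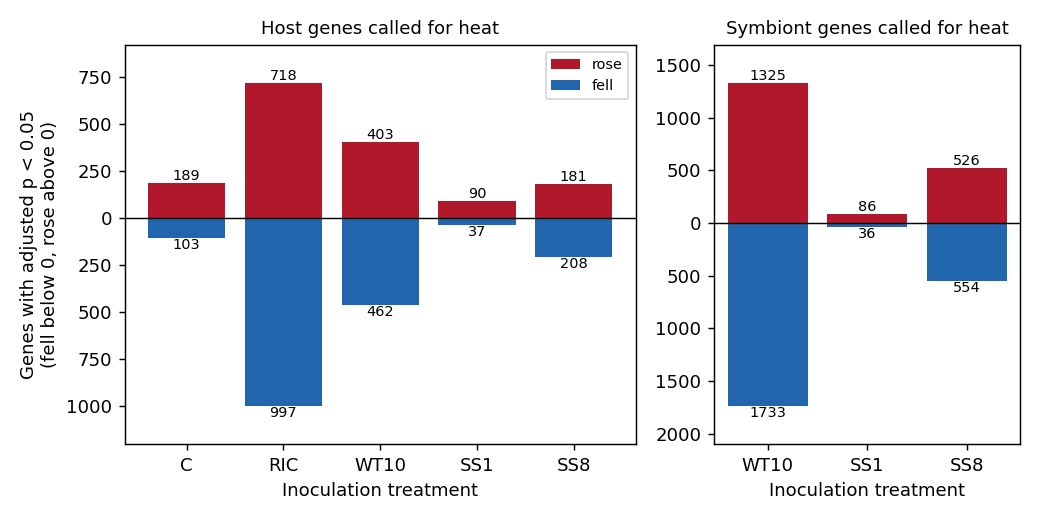
Number of genes called between elevated and ambient libraries (y axis, adjusted p below 0.05), in the host (left) and the symbiont (right), by inoculation treatment (x axis). Red bars above 0 count genes that rose and blue bars below 0 genes that fell; WT10 has 3058 symbiont calls and SS1 122.

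The largest rise among well-expressed host genes in C libraries was that of Pdae1385, from 49.0 CPM ± 20.1 (SD, n = 6) to 1090 CPM ± 404 (SD, n = 4), a log2 fold change of 4.46 (SE 0.51, edgeR adjusted p = 1.38e-06). It also rose in RIC (log2 3.28), WT10 (3.23) and SS1 (2.10) libraries, and in SS8 its log2 change was 1.71 with an adjusted p of 0.0613. Pdae16153 rose by 3.78 on the log2 scale in C libraries (SE 0.98, adjusted p = 0.0371), a call that did not pass when any of 8 of the 10 libraries was left out (adjusted p up to 0.113). Pdae81 fell by 3.43 in C (SE 0.75, adjusted p = 0.0117) and by 5.38 in RIC libraries, and its log2 change in SS1 was -0.53 (adjusted p = 0.839). The SS1 values of Pdae1385 and Pdae81 include elevated nubbin L1334, which resembled ambient libraries. Pdae1385 was at 49 CPM in L1334 and at 295 to 428 CPM in the other elevated SS1 libraries. Pdae6625 fell by 2.82 in C libraries (SE 0.63, adjusted p = 0.0133). The calls of Pdae81 and Pdae6625 in C were lost without 2 and 3 single libraries, at adjusted p up to 0.0617 and 0.0682.

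The number of host genes called depended on single libraries. In C it was 178 without ambient L1308, and 153, 135, 111 and 157 without elevated I996, J1066, L1305 and L1339. In RIC it was 1037 without ambient I989, and 1056 and 1130 without elevated L1269 and L1290. In WT10 it was 575, 525 and 488 without ambient J1049, J1093 and L1340, and 513 and 451 without elevated L1320 and L1321. In SS8 it was 134 and 183 without ambient I937 and L1258, and 128 and 122 without elevated I921 and L1322. In SS1 it was 313 without elevated L1334 and between 20 and 83 without any other library, ambient I954, J1062, L1268 and L1331 and elevated I978, J1056, J1065 and L1261 among them. When only the compared groups were fitted, 2 genes were called in SS8 and 0 in SS1 libraries, against 2248 in WT10. DESeq2 called 613 genes in C libraries, of which 324 rose and 289 fell, a more even split than edgeR's.

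EdgeR with all 48 libraries fitted called no host gene for a difference in the heat response between treatments, and DESeq2 called up to 19. For RIC against C the count was 0 by edgeR (1680 genes at an unadjusted p below 0.05) and 19 by DESeq2. For SS1 against WT10 it was 0 (591 genes) and 3 by DESeq2, and for SS8 against WT10 it was 0 (2145 genes) and 18 by DESeq2, while edgeR called 7, all with a higher log2 change in SS8, when only these groups were fitted, 1 with the nubbins of a colony summed, and 5, 2 and 1 without elevated SS8 J1033, elevated SS8 I921 and ambient SS8 I948. For the mean of SS1 and SS8 against WT10 it was 0 (1210 genes) and 2 by DESeq2. At an unadjusted p below 0.05 chance alone gives about 5% of the tested genes, and the observed percentages were 8.43, 2.97, 10.77 and 6.07. On simulated counts of this size, changed genes were drawn from those at or above the median expression. Of these, the test of SS1 against WT10 recovered 84.8% whose heat responses differed 4-fold, 22.4% that differed 2-fold and 4.5% that differed 1.5-fold. Most differences of 2-fold or less were thus missed in that test. The other differences in heat response were not simulated. The larger number of calls in WT10 than in SS1 does not by itself show a difference in response.

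RIC nubbins were compared with C nubbins at 27 °C. They differed by chemical bleaching, by inoculation with native symbionts and by tank, which cannot be told apart here. Of the host genes tested, 884 were called, 516 higher and 368 lower in RIC, with a median absolute log2 fold change of 0.79 (edgeR, adjusted p below 0.05). RIC nubbin L1283 belongs to the lower-numbered host set of colony L and the C nubbins of that colony to the higher one. With these sets as separate blocks 952 genes were called. The count was 0 when only the ambient RIC and C groups were fitted and 1 when the nubbins of a colony were summed. It was 172 without RIC nubbin I989, in which exons numbered last in their gene held 49.3% of host counts against 35.8% to 38.1% in the other ambient RIC libraries, 1772 without RIC nubbin I939, 586 without RIC nubbin L1283, and 486 and 543 without C nubbins J1075 and L1304. Inoculation with WT10 in place of native symbionts, compared as WT10 with RIC at 27 °C, gave 142 calls, 58 higher and 84 lower in WT10. How far WT10 replaced the native symbionts in these nubbins is not known from this comparison. The count was 1 when only these groups were fitted. It was 873, 266, 64 and 13 without RIC nubbins I939, J1028, L1283 and L1312, and 7, 51, 46, 63 and 7 without WT10 nubbins I935, J1049, J1093, L1307 and L1340.

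Host expression was compared between heat-evolved and wild-type strains at each temperature. At 27 °C, SS1 and WT10 nubbins differed in 0 host genes (647 at an unadjusted p below 0.05; 1 by DESeq2) and SS8 and WT10 nubbins in 6, of which 5 were higher in SS8 (edgeR; 7 with RLE normalization, 5 higher and 2 lower; 342 by DESeq2, 214 higher and 128 lower). The 6 became 248 without SS8 nubbin L1288, 0 without SS8 nubbin J1098 or L1258 or WT10 nubbin J1049, J1093 or L1340, and 1 without SS8 nubbin I937 or WT10 nubbin I935 or L1307. Both ambient SS8 nubbins of colony L (L1258 and L1288) belong to its lower-numbered host set and both ambient WT10 nubbins (L1307 and L1340) to the higher one, which the colony term does not remove, and with these sets as separate blocks 1 gene was called. The heat contrast in SS8 parts the sets in the same way, with elevated L1322 in the higher one. The heat contrast in RIC parts them in part. Its ambient nubbins L1283 and L1312 belong to different sets, and its elevated nubbins L1269 and L1290 to the lower one. At 32.2 °C, SS8 and WT10 nubbins differed in 0 host genes (451 at an unadjusted p below 0.05 by edgeR; 5 by DESeq2) and SS1 and WT10 nubbins in 1 (11 by DESeq2, 6 higher and 5 lower in SS1). This gene, Pdae9495, was at 222 CPM ± 110 (SD, n = 5) in elevated SS1 and 738 CPM ± 163 (SD, n = 5) in elevated WT10 libraries, a log2 difference of -1.73 (SE 0.29, edgeR adjusted p = 0.011). The call was lost when only these groups were fitted (adjusted p = 0.763), and another split of the same libraries gave 3 calls. It was also lost without SS1 nubbin J1065 (adjusted p = 0.0673) or WT10 nubbin L1321 (adjusted p = 0.063), and the log2 difference was -1.48 without SS1 nubbin L1334. Pdae9495 was also higher in ambient WT10 than in ambient RIC libraries, at 321 CPM ± 31.8 (SD, n = 5) against 85.5 CPM ± 36.5 (SD, n = 5), a log2 difference of 1.90 (edgeR adjusted p = 0.00208). Ambient SS1 libraries held 168 CPM ± 27.7 (SD, n = 4), ambient SS8 libraries 242 CPM ± 50.1 (SD, n = 5) and ambient C libraries 59.1 CPM ± 18.6 (SD, n = 6). Elevated SS8 libraries held 379 CPM ± 75.5 (SD, n = 4), elevated RIC libraries 169 CPM ± 22.3 (SD, n = 5) and elevated C libraries 125 CPM ± 41.4 (SD, n = 4).

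**Figure D4:**
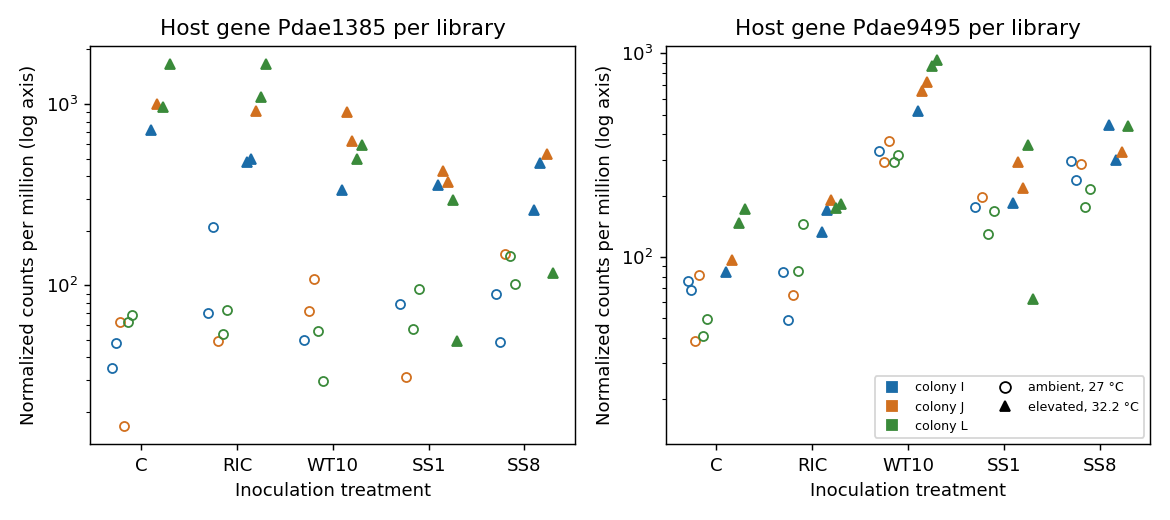
Normalized CPM on a log axis of the host genes Pdae1385 (left) and Pdae9495 (right) in each library, by inoculation treatment. Open circles are ambient and filled triangles elevated libraries, coloured by colony; Pdae9495 lies highest in elevated WT10 libraries, from 523 to 928 CPM, and 1 elevated SS1 library, L1334, lies at 62.2 CPM.

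The symbiont counts of an inoculated nubbin could come from the inoculated strain and from native symbionts that survived bleaching. Of 285855 symbiont exons with a count, 123798 had none in the 6 ambient C libraries, and the percent of a library's symbiont counts in these exons was used as a measure of RNA unlike that of the native symbionts. It is 0 in ambient C libraries by construction. In elevated C libraries it was 0.4% ± 0.0835 (SD, n = 4). It was 0.803% ± 0.612 (SD, n = 5) in ambient and 2.05% ± 0.621 (SD, n = 5) in elevated WT10 libraries (exact two-sided permutation p = 0.0159, adjusted p = 0.0635 over 4 tests). In SS1 libraries it was 1.03% ± 0.913 (SD, n = 4) against 1.7% ± 0.955 (SD, n = 5) and in SS8 libraries 1.1% ± 0.576 (SD, n = 5) against 1.55% ± 0.638 (SD, n = 4), which did not differ by more than the spread (exact permutation p = 0.349 and 0.31). In RIC libraries the median was 0.229% (0.207 to 1.07, n = 5) in ambient and 0.513% (0.417 to 0.84, n = 5) in elevated libraries (exact two-sided permutation p = 0.397 for the difference in means, adjusted p = 0.397 over 4 tests). Some inoculated libraries lay as low as ambient RIC libraries: ambient WT10 nubbin I935 held 0.184%, ambient SS1 nubbin J1062 0.232%, ambient SS8 nubbin I948 0.236% and elevated SS1 nubbin L1334 0.226%, below the lowest elevated RIC library at 0.417%.

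**Figure D5:**
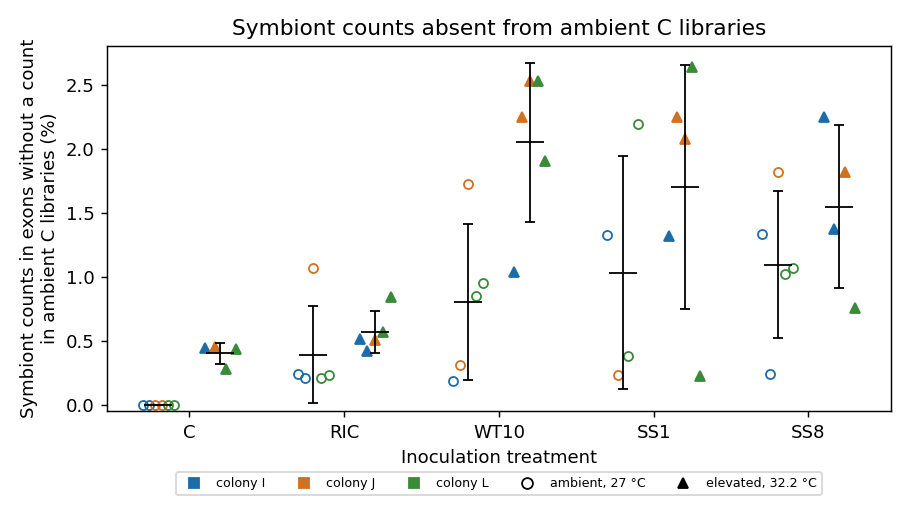
Percent of a library's symbiont counts in exons that had no count in ambient C libraries (y axis), by inoculation treatment (x axis). Symbols, colours and bars are as in the plot of symbiont share; ambient C libraries are at 0 by construction and elevated WT10 libraries average 2.05%.

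Symbiont genes were called for heat in nubbins inoculated with WT10, SS1 and SS8. Of 23606 symbiont genes tested, 3058 were called in WT10 libraries (1325 rose and 1733 fell), 1080 in SS8 (526 rose and 554 fell) and 122 in SS1 (86 rose and 36 fell), by edgeR's quasi-likelihood test at an adjusted p below 0.05. With RLE normalization in place of TMM, 1654 rose and 1385 fell in WT10, so the balance of directions depends on the scaling. In SS8 it turned as well, to 646 rising and 467 falling with RLE normalization. DESeq2 gave 2327 rising and 1895 falling genes in WT10, and 948 and 637 in SS8. In total 114 genes were called in all 3 treatments, 81 rising and 33 falling in each. WT10 and SS8 shared 739 called genes, all in the same direction, against 70.2 for independent lists. Of the 122 called in SS1, 119 were shared with WT10 against 7.5, and 115 with SS8 against 2.8, all in the same direction. The largest changes among well-expressed genes in WT10 libraries were rises of evm.model.scf7180000356037.2, from 5.94 CPM ± 5.17 (SD, n = 5) to 117 CPM ± 71.8 (SD, n = 5; log2 4.28, SE 1.04, edgeR adjusted p = 0.00899), and of evm.model.scf7180000357362.19 by 4.06 on the log2 scale (SE 0.74, adjusted p = 0.0012). Genes evm.model.scf7180000356151.4 and evm.model.scf7180000356290.12 fell by 3.45 (SE 0.77, adjusted p = 0.00519) and fell by 3.37 (SE 0.93, adjusted p = 0.0189), the latter call being lost without ambient J1049 or elevated J1076 or L1320 (adjusted p up to 0.0625).

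The percent of counts in exons without a count in ambient C libraries was taken as a composition covariate, an alternative added after the data were seen. With it 1569 symbiont genes were called in WT10, 530 in SS1 and 2023 in SS8 libraries. The rise of evm.model.scf7180000356037.2 was then 1.56 (adjusted p = 0.0596) and the fall of evm.model.scf7180000356290.12 was -1.19 (adjusted p = 0.0718). The mean of this percent was higher in elevated (2.05%) than in ambient (0.803%) WT10 libraries. It was 0.4% in elevated C libraries, which were never inoculated. The covariate can therefore take up part of the heat change itself. The count in SS1 libraries rested on nubbin L1334: without it 1654 genes were called, leaving out any other SS1 library gave 1 to 79, and 0 were called by edgeR when only the SS1 groups were fitted. In WT10 the count was 1722 and 1584 without ambient I935 and J1049, and 2020 and 1840 without elevated J1076 and L1320. In SS8 it was 606 without ambient I948.

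EdgeR as planned called no symbiont gene for a difference in the heat response between strains, and with the composition covariate it called 1 for the mean of SS1 and SS8 against WT10. The counts were 0 by edgeR for SS1 against WT10 (876 genes at an unadjusted p below 0.05; 3 by DESeq2), 0 for SS8 against WT10 (1093 genes; 1 by DESeq2) and 0 for the mean of SS1 and SS8 against WT10 (1081 genes; 2 by DESeq2). On simulated counts the test of SS1 against WT10 recovered 68.2% of symbiont genes with a 4-fold difference in response and 14.9% of those with a 2-fold difference. These genes were drawn from those at or above the median expression. Inoculated libraries with little RNA unlike that of native symbionts could also hide a difference between strains.

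Strains were compared within a temperature to ask which symbiont genes separate them. Some inoculated libraries lay as low as ambient RIC libraries on the measure of RNA unlike that of native symbionts. Few or no calls therefore need not mean that the strains are alike. At 27 °C edgeR called 0 genes between SS1 and WT10 libraries (299 at an unadjusted p below 0.05; 16 by DESeq2) and 0 between SS8 and WT10 libraries (492; 16 by DESeq2). At 32.2 °C, 9 genes were called between SS1 and WT10 libraries, all lower in SS1, and DESeq2 called 69, of which 16 were higher and 53 lower. The summed expression of the 9 genes, which were chosen for this difference, was 11.2 CPM ± 7.05 (SD, n = 5) in elevated SS1 and 290 CPM ± 101 (SD, n = 5) in elevated WT10 libraries. It was 43.2 CPM ± 22.5 (SD, n = 4) in elevated SS8 and 22.9 CPM ± 3.59 (SD, n = 6) in ambient C libraries. In elevated C libraries it was 11 CPM ± 4.59 (SD, n = 4) and in elevated RIC libraries 23.2 CPM ± 14.6 (SD, n = 5). Elevated SS1 libraries thus lay near those of nubbins not given *C. proliferum*. At ambient temperature the sum was 24.8 CPM ± 7.4 (SD, n = 4) in SS1, 52 CPM ± 18.2 (SD, n = 5) in SS8 and 117 CPM ± 79.7 (SD, n = 5) in WT10 libraries, with 23.1 CPM in the lowest WT10 library. The count was 0 when the nubbins of a colony were summed (edgeR; 1799 genes at an unadjusted p below 0.05 with nubbins kept apart). The 9 became 4 without elevated SS1 nubbin J1065 or L1261 and 5 without elevated WT10 nubbin L1320. Between elevated SS8 and WT10 libraries 1 gene was called, evm.model.scf7180000356980.13, at 0.927 CPM ± 1.44 (SD, n = 4) in SS8 and 53.6 CPM ± 28.7 (SD, n = 5) in WT10 libraries (log2 -5.05, SE 0.82, edgeR adjusted p = 0.0441; 29 genes by DESeq2, 18 higher and 11 lower). It was also among the 9 called for SS1, with a log2 difference of -4.50 (adjusted p = 0.00149). Its call for SS8 was lost without SS8 nubbin I921, J1033 or L1322 or WT10 nubbin J1045, J1076, L1320 or L1321 (adjusted p up to 0.146).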

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

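The tests of treatment and RNA quality in colony L, and of the host heat score and the exchange of nubbin L1334, were chosen after the result was seen. Of 59 combinations of group and measure, 3 held a library far from the rest, where chance gives about 1 in 20. Ambient RIC nubbin J1028 had 1.07% of its symbiont counts in exons without a count in ambient C libraries, against 0.206% to 0.236% in the other ambient RIC libraries. Elevated C nubbin L1305 had 0.275%, against 0.433% to 0.448% in the other elevated C libraries. Ambient RIC nubbin I989 had 49.3% of host counts in the last-numbered exons of genes, against 35.8% to 38.1% in the others of its group.

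The symbiont counts of C and RIC libraries, outside the planned comparisons, also changed with heat. Fitted alone, these 20 libraries gave 3258 called symbiont genes of 21596 in C (1644 rose and 1614 fell) and 3223 in RIC (1344 rose and 1879 fell), by edgeR at an adjusted p below 0.05. Of these, 1829 were shared and 1828 had the same direction, against 242.7 for independent lists. The difference between C and RIC in heat response gave 0 calls (edgeR, 1430 at an unadjusted p below 0.05; DESeq2 was not run here). Elevated RIC nubbins L1290 and L1269 held only 43357 and 357833 symbiont counts, which limits the RIC results.

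Host libraries of colony L formed 2 sets that followed the nubbin number. Between the sets, 154 genes were silent in one and expressed in the other, against 206 between colonies I and J and 0 between lower and higher numbers within colony I or J. Treatment is argued against because 3 of the 10 groups held libraries of both sets: ambient RIC, ambient SS1 and elevated SS1. Elevated SS1 did so only through nubbin L1334, whose label is in doubt. RNA quality is argued against because the share of counts in last-numbered exons was 36.1% ± 1.46 (SD, n = 7) and 36.6% ± 1.5 (SD, n = 12) (exact two-sided permutation p = 0.448), with overlapping values. A candidate explanation is that nubbins of 2 host genotypes carry the name of colony L. It stays a hypothesis, since no genotype was measured here.

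The elevated SS1 library L1334 resembled ambient libraries with native symbionts. Its host heat score, the mean log2 change over 557 genes chosen without SS1 libraries, was 0.15, inside the -0.29 to 0.48 of ambient libraries and below the 0.73 of the lowest other elevated library. A heated nubbin recolonized by native symbionts is argued against by its symbiont heat score of 0.03 over 5087 genes, where elevated RIC libraries lay between 0.74 and 1.22. An exchange with an ambient library of the same host set is argued against by the highest score among those 6 libraries, 0.23. What stays open is that the library or nubbin may not be one of the heated SS1 nubbins.

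The symbiont heat calls in WT10 could reflect a change in the mix of symbionts or a response of the algae. Lower depth in heated libraries is argued against as the main cause: after thinning the 10 libraries to 1160355 counts, the number of calls was a median of 76.4% (75.8 to 77.1 over 5 draws) of the 4298 called without thinning with only the WT10 groups fitted (3058 were called with all 28 libraries fitted). Across 21252 genes the heat change correlated at 0.58 with the slope on the mix in ambient SS1 and SS8 libraries, and across 20416 genes at 0.42 with the heat change in C libraries, which share no library with it (Pearson's r; genes are not independent replicates). Both explanations stay open and may hold together.

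Among 22 splits of the compared libraries, the most that such a set can show is 1 of 22 for each contrast, not adjusted over the 25 contrasts. Labels moved without regard to colony or to the 2 host sets of colony L, so the splits do not keep the pairing by colony. The real split was the only 1 as large for host heat calls in C (292, highest other split 43), RIC (1715, 290), WT10 (865, 0) and SS8 (389, 54). The same held for symbiont heat calls in WT10 (3058, 0) and SS8 (1080, 4). Such a result argues against chance for a single contrast but cannot exclude it over 25. The host calls in SS8 fell to 2 with only the compared groups fitted, so chance is left open for them. Of the 389, 109 were shared with WT10 in the same direction, against 8.5 for independent lists. The real split was also the only 1 as large for ambient host RIC against C (884, 572) and SS8 against WT10 (6, 0) and for elevated symbiont SS1 against WT10 (9, 1). Chance is left open for these 3, because the first gave 0 calls with only the compared groups fitted and 1 with nubbins summed, and the second gave 0 with only the compared groups fitted, with thinned counts and without any of 5 single libraries, and the last gave 0 with nubbins summed (edgeR in each case; 1675, 342 and 69 genes by DESeq2, and 4343, 3556 and 1799 at an unadjusted p below 0.05 with all nubbins and groups kept). It is not excluded, with 2 splits as large, for ambient WT10 against RIC (142, 425), host elevated SS1 against WT10 (1, 3) and symbiont elevated SS8 against WT10 (1, 1). Heat calls in SS1 also had 2 splits as large, in the host (127, highest other 188) and the symbiont (122, 1069), so the splits do not exclude chance for these counts. Of the called genes, 80 of the 127 and 119 of the 122 were shared with WT10 in the same direction, against 2.7 and 7.5 for independent lists. The contrasts have no library in common but came from 1 fit per organism. A heat response in SS1 would give such sharing. In the symbiont so could a chance difference in the mix, whose slope correlated with the heat change in WT10. In the symbiont the sharing therefore does not exclude chance. In the host, a mean log2 heat change was scored over 557 genes chosen without SS1 libraries. It was 0.73 to 1.21 in the 4 elevated SS1 libraries other than L1334, and 0.15 in L1334. Ambient libraries lay between -0.29 and 0.48. These values argue against chance for the host response of those genes in those 4 libraries. The splits leave the count of 127 open. The larger host split in SS1 exchanged ambient L1268 with elevated L1334, which set the lower-numbered nubbins of colony L against the higher-numbered ones. The split with 1069 symbiont calls moved ambient I954 and L1331 and elevated J1056 and L1334. Why these splits gave more calls was not tested. For the contrasts with 0 calls by edgeR, all 22 splits gave as many by definition, since no count lies below 0. The splits therefore decide nothing for them. The highest other split gave 1 for the host SS8 and the symbiont SS1 heat difference from WT10 and for ambient symbiont SS1 against WT10, 4 for ambient host SS1 against WT10, 9 for elevated host SS8 against WT10, and 0 for the others. Counts at an unadjusted p below 0.05 and by DESeq2 for these contrasts stand with each comparison.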

How the results depend on the processing

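The settings with colony L as 2 blocks, thinned host counts, the composition covariate and doubted libraries left out were chosen after the data were seen. No difference in symbiont share between temperatures and no named gene changed sign. The difference between SS8 and WT10 in how far heat lowered the share was 0.609 points and, as a log2 ratio of symbiont to host counts, -0.47 (exact permutation p = 0.891 and 0.603). The balance of symbiont heat calls in WT10 did turn, from 1325 rising and 1733 falling genes to 1654 and 1385 with RLE normalization and to 2327 and 1895 with DESeq2, and that in SS8 from 526 and 554 to 646 and 467 and to 948 and 637. RLE normalization kept all 25 counts within 1.5 times, and the log2 ratio and permutation within colony changed no call of symbiont share. Where a cause is not given by the setting itself, the cause was not tested. Symbiont depth in the heated libraries that entered the 10 planned symbiont contrasts went down to 289793 counts (SS8 nubbin L1322), which limits them.

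DESeq2 called, in the host, 613 genes for heat in C, 1409 in WT10, 368 in SS1 and 814 in SS8, 19, 3, 18 and 2 for the heat differences RIC-C, SS1-WT10, SS8-WT10 and their mean, 1675 for ambient RIC-C, 691 for WT10-RIC, 1 and 342 for ambient SS1-WT10 and SS8-WT10, and 11 and 5 for the elevated ones. In the symbiont it called 472 for heat in SS1, 3, 1 and 2 for the heat differences, 16 and 16 at ambient and 69 and 29 at elevated temperature.

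With only the compared groups fitted, host counts were 316 in RIC, 2248 in WT10, 0 in SS1, 2 in SS8, 7 for the SS8-WT10 heat difference, 0 for ambient RIC-C, 1 for WT10-RIC, 0 for ambient SS8-WT10 and 0 for elevated SS1-WT10. Symbiont counts were 0 in SS1, 414 in SS8 and 11 for elevated SS8-WT10. The symbiont mean of SS1 and SS8 against WT10 uses all 28 libraries and was not rerun.

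With no replicate block (the colony term left out), host counts were 84 in C, 748 in RIC, 247 in WT10, 18 in SS1, 87 in SS8, 336 for ambient RIC-C, 2 for WT10-RIC and 0 for SS8-WT10, and 2 symbiont genes were called for ambient SS1-WT10. It moved no other count by over 1.5 times. With the nubbins of a colony summed, host counts were 135 in C, 765 in RIC, 343 in WT10, 241 in SS1, 1 for the SS8-WT10 heat difference, 1 for ambient RIC-C, 2 for WT10-RIC, 1 and 1 for ambient SS1-WT10 and SS8-WT10, and 2 for elevated SS1-WT10. Symbiont counts were 930 in WT10, 20 in SS1, 223 in SS8, 1 for ambient SS1-WT10, and 0 and 0 at elevated temperature. With nubbins averaged, the share differences were -32.08 in C, -35.3 in RIC, -25.27 in WT10 and -23.21 in SS8 points (smallest possible exact permutation p 0.1), and host inoculation went with 6.42% of variance (permutation p = 0.1497).

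Without the low-count filter, symbiont counts were 9 and 14 at ambient and 24 and 4 at elevated temperature. With all 48 libraries fitted they were 278 for heat in SS1, 5 and 5 at ambient and 29 and 3 at elevated temperature. With the composition covariate they were 1569 in WT10, 530 in SS1, 2023 in SS8, 1 for the mean heat difference, 31 and 34 at ambient and 98 and 37 at elevated temperature. With colony L as 2 blocks, host counts were 466 in C, 223 in SS1 and 1 for ambient SS8-WT10, 0 symbiont genes were called for elevated SS8-WT10, and host inoculation went with 3.85% of variance (permutation p = 0.097). With doubted libraries left out, host counts were 747 in C, 1133 in RIC, 1766 in WT10, 790 in SS1, 1056 in SS8, 329 for ambient RIC-C, 344 for WT10-RIC and 303 for SS8-WT10, and symbiont counts 2009 in SS1, 1680 in SS8, 2 for ambient SS1-WT10 and 0 for elevated SS8-WT10. With host counts thinned, ambient SS8-WT10 gave 0. With 1 minus Spearman's correlation, the host interaction went with 3.14% of variance (permutation p = 0.0284).

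Leaving out 1 library at a time gave host ranges of 111 to 421 in C, 1037 to 2160 in RIC, 451 to 775 in WT10, 20 to 313 in SS1, 122 to 483 in SS8, 172 to 1772 for ambient RIC-C, 7 to 873 for WT10-RIC, 0 to 248 for ambient SS8-WT10, 0 to 5 and 0 to 1 for the SS8-WT10 and mean heat differences, and 0 to 3 and 0 to 1 for elevated SS1-WT10 and SS8-WT10. Symbiont ranges were 1584 to 3629 in WT10, 1 to 1654 in SS1, 606 to 968 in SS8, 0 to 3 and 0 to 4 at ambient and 4 to 9 and 0 to 5 at elevated temperature. Share differences ranged from -33.51 to -30.65 in C, -37.52 to -32.3 in RIC, -24.97 to -23.13 in WT10, -23.09 to -12.44 in SS1 and -26.26 to -21.52 in SS8. Of these refits 281 of the counts and shares kept their side, 91 moved by over 1.5 times and 1 passed that had not. For named genes 74 kept their call and 25 lost it.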

Other observations

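None of the tests in this part was planned before the data were examined, but the predictions for neighbouring genes and exon numbers were written before their results were seen. Symbiont heat calls in C and RIC libraries overlapped those in WT10 libraries, which can hold native symbionts too. C and WT10 libraries shared 1187 called symbiont genes, 1180 in the same direction, against 218.8 for independent lists, and RIC and WT10 shared 1167, of which 1161 had the same direction, against 224.3. These come from fits with no library in common.

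Strains were also compared with both temperatures averaged, by edgeR alone. Between SS1 and WT10 libraries 39 genes were called (6 higher and 33 lower in SS1), between SS8 and WT10 23 (13 higher and 10 lower in SS8), and between SS8 and SS1 4, all higher in SS8. In the host 1 gene was called between SS1 and WT10, 0 between SS8 and WT10 (edgeR, 1496 at an unadjusted p below 0.05) and 0 between SS8 and SS1 (1097).

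In 8 symbiont genes the mean was at least 10 CPM in elevated WT10, SS1 and SS8 libraries and every other library was below 1 CPM. No gene met the reverse rule, with ambient in place of elevated inoculated libraries. Elevated SS1 nubbin L1334 had a count in 0 of the 8 genes and elevated SS8 nubbin L1322 in 3, elevated WT10 nubbin L1320 in 7 and every other elevated inoculated library in all 8.

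Called genes lay beside one another more often than by chance, taking consecutive identifiers as neighbours. For host heat in RIC, 184 pairs of consecutive identifiers were called in the same direction, against a mean of 64.1 (40 to 93) over 1000 shuffles of the calls. For symbiont heat in WT10 there were 206 pairs on the same scaffold, against 109.8 (80 to 143). The hypothesis that neighbouring genes change together with heat may hold, but consecutive identifiers could also be parts of the same gene or near-identical copies, which was not tested. The hypothesis that symbiont genes that rose with heat in WT10 have fewer exons than those that fell was not borne out. The medians were 14 and 13 exons, against 17 over tested genes (permutation p = 0.09 for the difference in means).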
